A study of Zea mays with 6 samples.

How the data were processed

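The series measured messenger RNA in young maize tassels, the male inflorescence, of 2 to 4 mm length from greenhouse-grown plants in the B73 inbred background. There were 3 wildtype libraries of 5 pooled tassels each and 3 libraries of 10 pooled tassels each from plants heterozygous for both Bif1 and Bif4. Per the labels' protocols, RNA was taken with a column kit and DNase, and stranded poly(A) libraries were made. Groups and replicate numbers come from the sample titles and genotype labels. The labels do not say whether the plants of a group were grown or harvested on separate days, so p-values measure the spread between these pools.

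Per the submitters' processing notes, Trimmomatic, TopHat2 2.1.1, HTSeq and DESeq2 were used. The order of these steps, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. A single deposited table holds, per gene, 6 columns of read counts that the authors divided by 1 size factor per library, which were treated as a signal and not as raw counts. The deposited table also gives the mean over the 6 libraries, and the authors' log2 fold change with its standard error, Wald statistic (a score) and p-value before and after adjustment. All columns of per-sample values were mapped to a sample by name.

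In each of the 6 columns, 100.0% of the values were whole multiples of a single step, within 1e-06 reads, so the read counts were recovered by division. The recovered totals were 21047225, 24636859 and 21631540 reads for wildtype replicates 1 to 3 and 23431863, 23066609 and 23196296 for Bif1;Bif4 replicates 1 to 3. The 10 most abundant genes took between 1.85% and 1.97% of the reads. A value of 0 allows up to 3 reads, which is 2.75 to 3.30 normalized counts depending on the library. This limit covers counting error only.

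Gene names came from a table of RefSeq genes of the Zm-B73-REFERENCE-NAM-5.0 assembly and were used as names only, with no coordinates, since the build behind the deposited identifiers is not given. Of the identifiers, 18476 matched exactly 1 gene of that table, 521 matched more than 1 and were left unnamed, and 20308 matched none. An informative symbol or synonym was found for 2689 genes. Members of recent gene duplicates can share reads, and how the counting split them is not given, so values of near-identical copies are uncertain.

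As fixed before the data were examined for values that are normalized and not raw counts, the main test was limma 3.58.1 (trend and robust) on log2(value + 1). Genes needed a normalized count of at least 10 in at least 3 libraries, which kept 21924 genes holding 99.9% of the summed values. Fold changes are Bif1;Bif4 over wildtype on this scale, which understates changes of low genes. P-values are two-sided with Benjamini-Hochberg adjustment, and a gene is said to rise or fall where limma's adjusted p was under 0.05. From these libraries 3 data sets were simulated, each with 200 changed genes and 21682 to 21718 genes kept. The changed genes had a mean of at least 50 normalized counts, so recovery of lower genes was not simulated. Genes were drawn independently, with no library set apart from its group. Limma recovered 81.3% of the changes of 2-fold and 96.0% of those of 4-fold. In these simulations 8.39% of limma's calls were false, above the nominal level.

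Before the data were examined, 30 gene lists were fixed by symbol or pattern, and 2 of them matched no gene. Lists with at least 3 tested members were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry as alternatives. The genes named were BIF1, BIF4 and BA1, the 10 largest rises and 10 largest falls among called, named genes with no overlap of the groups and a mean of at least 50, and up to 3 called members per list, or the 2 most abundant members of a list with no call. Of the genes this rule takes, 1 is not reported here. Other genes are named as examples chosen after their values were seen. Some members were matched by a symbol that names more than 1 kind of gene, and the lists were also tested without them.

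Alternatives fixed beforehand were median-centred values and, on the recovered reads, DESeq2 1.42.0, limma-voom and edgeR 4.0.16 with relative log scaling. Also fixed beforehand were other filters and pseudocounts, the replicate number as a block, a stricter threshold, a fold minimum and leaving out each library. The edgeR quasi-likelihood test on recovered reads with TMM scaling, called the edgeR test below, was added after seeing the data. So was the removal of doubtful list members. Computation used R 4.3.3 and Python 3.11.15.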

Results

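Transcript levels were compared between wildtype tassels and tassels of Bif1;Bif4 double heterozygous plants, with 3 pooled libraries per genotype and 21047225 to 24636859 reads per library. Bif1 and Bif4 (Barren inflorescence) are dominant mutations in Aux/IAA repressors of auxin signalling that reduce the formation of branches and spikelets on the maize inflorescence. The series title concerns needle1, a gene for a mitochondrial ATPase needed for growth at high temperature. The comparison asks which transcripts differ in young tassels carrying both mutations.

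In Bif1;Bif4 tassels, 13 of 21 tested genes of axillary meristem formation and branching fell, and a few of them were nearly lost. The trehalose phosphate phosphatase gene ra3 (ramosa3, GRMZM2G014729) fell from 1801 ± 599 to 3.60 ± 1.49 normalized counts (SD, n = 3 in each group). BA1 (barren stalk1, GRMZM2G397518), a bHLH factor required for axillary meristem initiation, fell from 406 ± 97.3 to 4.23 ± 3.70, and ra1 (ramosa1, GRMZM2G003927) from 178 ± 52.5 to 1.95 ± 2.57. Genes that rose included the AGAMOUS-type gene MADS35, the glume regulator zmm19 and the meristem receptor gene fea3. Over all genes, 467 rose and 637 fell, of 21924 tested (limma, adjusted p under 0.05), and without wildtype replicate 2 the order turned, with 776 risen and 627 fallen.

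BIF1 itself (GRMZM2G130953) was measured at 650, 818 and 748 normalized counts in wildtype replicates 1 to 3 and at 267, 166 and 158 in Bif1;Bif4 replicates 1 to 3. It fell by 1.94 on the log2 scale (SE 0.21, limma adjusted p = 0.0029). BIF4 (GRMZM5G864847) was at 346, 405 and 350 in wildtype and at 280, 151 and 230 in Bif1;Bif4, a log2 fold change of -0.77 (SE 0.22) that did not pass the test (limma adjusted p = 0.086), although each Bif1;Bif4 library lay below each wildtype library. The mutations alter the proteins, so transcript level does not check the genotype labels. The 3 tested Aux/IAA genes of the fixed list were BIF1, BIF4 and IAA12. Of these 1 fell over all genes tested, BIF1, and 2 when adjusted over the list alone, BIF1 and BIF4. The list result therefore largely restates the mutated genes. The list was lower by camera (adjusted p = 0.011), with adjusted p = 0.27 with an estimated correlation, and adjusted p = 0.053 without wildtype replicate 2.

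**Figure D1:**
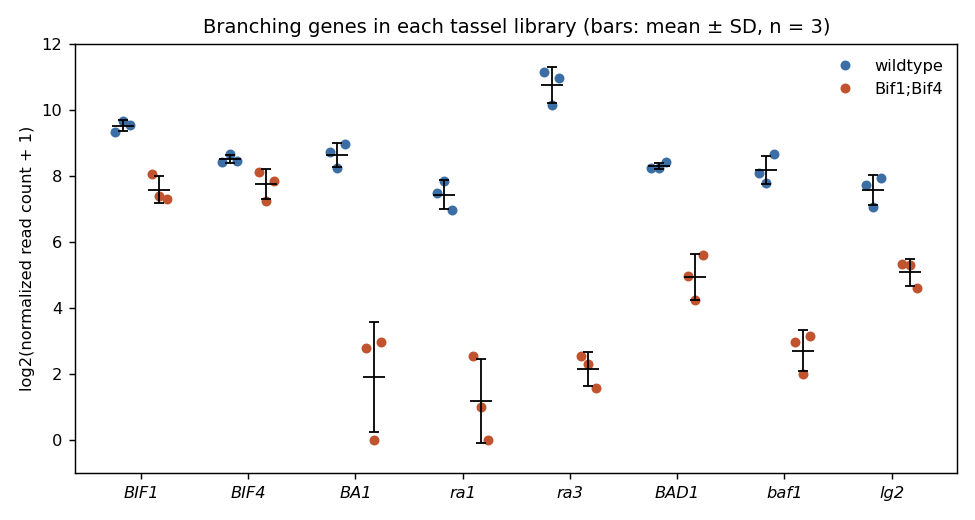
Normalized read counts on a log2(count + 1) scale for 8 genes in each library. Points are the 3 wildtype and 3 Bif1;Bif4 libraries, and bars give the mean ± SD of the logged values. BA1, ra1, ra3 and baf1 are near the floor in Bif1;Bif4, while BIF4 differs least of the 8.

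Of the 21 tested genes of axillary meristem formation and branching, 13 fell, 0 rose and 8 did not pass the test. Adjusted over the list alone, 14 fell and 3 rose. The list includes BIF1, which is among the 13, and BIF4. Besides ra3 (log2 fold change -8.61, SE 0.34, limma adjusted p = 7.3e-05), BA1 (-6.73, SE 0.79, adjusted p = 0.0090) and ra1 (-6.26, SE 0.62, adjusted p = 0.0021), the TCP gene BAD1 (branch angle defective1, GRMZM2G110242) fell by 3.36 on the log2 scale (SE 0.32, adjusted p = 0.0016). The spikelet meristem gene bd1 (branched silkless1) fell by 5.01 on the log2 scale, from a low 54.3 ± 52.6 with 114 in wildtype replicate 2 against 31.9 and 16.5, and by 4.26 without that library. The leaf and branch genes lg2 (liguleless2) and lg1 (liguleless1) fell from 197 ± 58.0 to 33.7 ± 8.85 and from 149 ± 60.2 to 40.9 ± 6.24, and the kinase gene bif2 (barren inflorescence2) fell by 1.39. The SBP genes ub2 and ub3 had log2 fold changes of 0.80 and 1.11 and did not pass (adjusted p = 0.11 and 0.13). Without wildtype replicate 2, where ub3 was at 1898 against 3441 and 4373 in the other wildtype libraries, ub3 rose (adjusted p = 0.032). The list was lower by camera (adjusted p = 2.7e-09), with adjusted p = 0.27 with an estimated correlation.

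Outside that list, baf1 (barren stalk fastigiate1, GRMZM2G072274), an AT-hook gene needed for ear formation, fell from 298 ± 93.7 to 5.87 ± 2.55, and the ovate family gene OFP28 from 163 ± 8.98 to 6.86 ± 3.38. Both boundary NAC and LOB genes of the fixed list fell, CUC2 (nam1) by 2.29 and LBD6 (indeterminate gametophyte1) by 1.37 on the log2 scale. TAB2 fell from 92.7 ± 37.2 to 9.47 ± 2.74. The polyamine oxidase gene MPAO fell by 4.74, from 1108 ± 1125, with 2398 normalized counts in wildtype replicate 2 against 593 and 332 in the others, and the edgeR test did not call it (adjusted p = 0.071).

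Meristem identity and size genes were lower as a list by camera (adjusted p = 8.3e-05), with adjusted p = 0.27 with an estimated correlation. Of 15 tested, 6 fell, 1 rose and 8 did not pass, and 7 fell and 1 rose when adjusted over the list alone. The KNOX homeobox genes knox4 (gnarley1) and lg4 fell by 1.37 and 1.45 on the log2 scale (limma adjusted p = 0.0034 and 0.0092). The most abundant KNOX gene, kn1 (knotted1), which marks meristem and stem tissue, was at 8969 ± 317 in wildtype and 7247 ± 566 in Bif1;Bif4, a log2 fold change of -0.31 that did not pass (adjusted p = 0.073). TD1 (thick tassel dwarf1), a CLAVATA1-type receptor, fell by 1.68, while fea3 (fasciated ear3), another receptor gene of meristem size control, rose from 327 ± 34.0 to 770 ± 182.

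Organ polarity genes were lower as a list by camera (adjusted p = 1.5e-04), with adjusted p = 0.27 with an estimated correlation. They had 5 of 13 fallen, 0 risen and 8 not past the test, and 8 fallen and 1 risen when adjusted over the list alone. The fallen genes were the YABBY genes yabby15 (881 ± 356 to 154 ± 26.6), YAB5, yab9 and yab10 and the KANADI gene mwp1 (milkweed pod1, 174 ± 4.65 to 47.4 ± 9.72). YABBY and KANADI genes pattern the sides of lateral organs. Wildtype replicate 2 held the highest values of yabby15, YAB5, yab9 and yab10. Without it 6 members fell.

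Floral MADS genes moved in both directions, with 3 risen, 5 fallen and 9 not past the test among 17, and 6 risen and 5 fallen when adjusted over the list alone. MADS36 fell from 7409 ± 285 to 2042 ± 355, and sts1 (zmm16), a PISTILLATA-type gene of stamens and lodicules, fell from 731 ± 90.5 to 253 ± 7.39. MADS35 (ZMM2) rose from 105 ± 27.9 to 329 ± 44.4 and zmm19 (the tunicate gene) from 1298 ± 377 to 3433 ± 393. The median log2 fold change was 0.14, with camera adjusted p = 0.98 and fry placing the list in the downward direction (adjusted p = 0.15). Among 22 SBP genes 2 rose, sbp2 and sbp29 by 1.49 and 0.98 on the log2 scale, 2 fell and 18 did not pass; 6 rose and 2 fell when adjusted over the list alone, and camera made no call (adjusted p = 0.38). Without wildtype replicate 2, 5 floral MADS genes and 4 SBP genes rose.

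**Figure D2:**
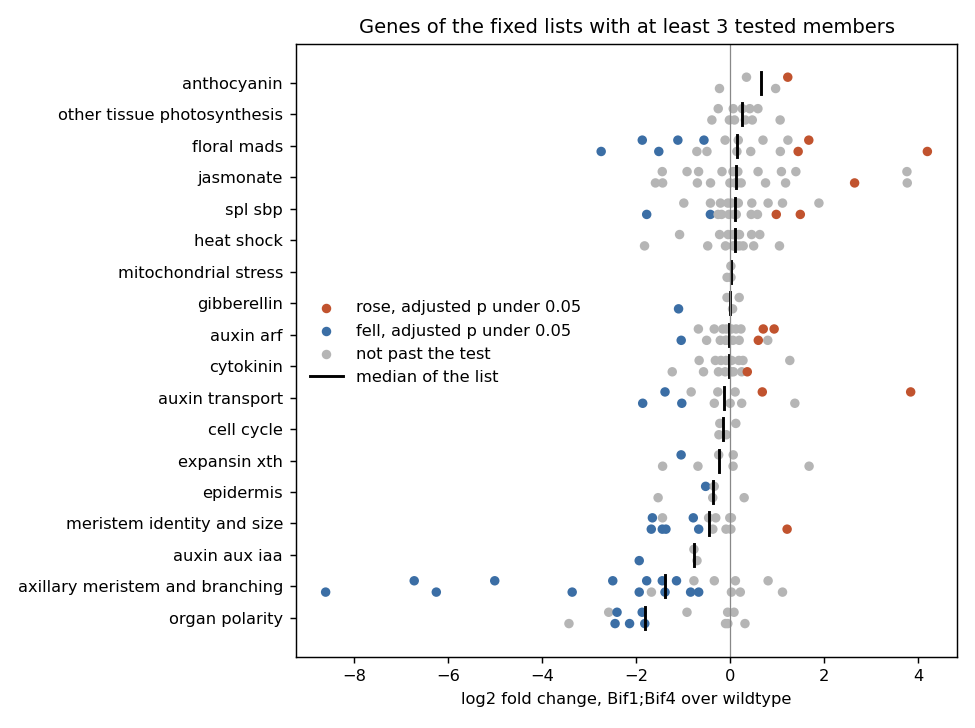
Log2 fold changes, Bif1;Bif4 over wildtype, of the tested genes of each fixed list with at least 3 tested members. Each point is a gene, coloured where limma's adjusted p was under 0.05, and black lines are list medians. Medians of organ polarity (-1.82) and of axillary meristem and branching (-1.39) were the lowest.

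Auxin genes did not move as a block. Of 18 tested auxin response factors 3 rose and 1 fell, over all genes and when adjusted over the list alone. ARF23 rose from 2615 ± 131 to 4991 ± 209 and ARF13 from 15609 ± 1086 to 25367 ± 1757, while ARF11 fell from 3374 ± 469 to 1641 ± 290, and camera made no call (adjusted p = 0.64). Among 12 genes of auxin transport 2 rose and 3 fell, and 2 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.59). The efflux carrier gene PIN10a rose from 3.05 ± 0.28 to 71.1 ± 55.4, with 57.3, 23.8 and 132 in Bif1;Bif4 replicates 1 to 3. Its wildtype values lie at the limit of a 0, so the size of this rise is not resolved. Symbols of the AUX kind, 6 of these 12, also name Aux/IAA genes, so AUX1 (fell by 1.86) and AUX6 (log2 fold change 0.68) are of uncertain identity. So is AUX9 (GRMZM2G048131, log2 fold change -1.03). These doubtful genes make up 1 of the 2 rises and 2 of the 3 falls over all genes. Camera without the doubtful members gave adjusted p = 0.43. The biosynthesis genes spi1 and Yucca6 and the conjugating gene GH3 had log2 fold changes of 0.02, 0.63 and 0.77 and did not pass. Adjusted over the list alone, 1 of the 2 biosynthesis genes rose. GH3 was the only tested gene of its list, so adjustment over that list leaves its unadjusted limma p of 0.020. Over all genes its limma adjusted p was 0.15.

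Of the epidermal genes, 1 of 5 fell, ocl4 by 0.53, and 4 fell and 1 rose when adjusted over the list alone. Camera placed the list lower (adjusted p = 0.023), with adjusted p = 0.27 with an estimated correlation and adjusted p = 0.057 without wildtype replicate 2. Of 4 anthocyanin genes, A1, for dihydroflavonol reductase, rose from 91.1 ± 10.8 to 213 ± 14.9, and 2 rose when adjusted over the list alone (camera adjusted p = 0.084). The cell wall gene expa2, the gibberellin synthesis gene d3 (dwarf3) and the pathogenesis gene PR10 fell by 1.05, 1.10 and 2.13, as the only calls among 7, 4 and 2 tested members, and d3 was not called without wildtype replicate 2 (adjusted p = 0.072). Without that library 2 epidermal genes fell, and 2 anthocyanin, 2 cytokinin and 1 expansin gene rose. In the cytokinin list, RR10 rose by 0.36 on the log2 scale and the 15 other members did not pass. Camera called none of the expansin, gibberellin and cytokinin lists (adjusted p = 0.27, 0.63 and 0.63).

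Genes of heat response and mitochondria, which relate to the series title, were also examined. NDL1 (GRMZM2G038401) was at 3499 ± 282 in wildtype and 3525 ± 214 in Bif1;Bif4 (log2 fold change 0.01, SE 0.09, limma adjusted p = 0.96). Of the 19 heat shock genes tested, 0 passed with limma, over all genes or when adjusted over the list alone, and 0 with edgeR, while 4 had an unadjusted p under 0.05. Without wildtype replicate 2, in which this list was low, HSP18 fell (adjusted p = 0.028). Over all 6 libraries hsp70-4 and HSP90-2 each had a log2 fold change of 0.06. Camera gave adjusted p = 0.63 for heat shock, 0.94 for the mitochondrial list of 3 genes and 0.38 for the cell cycle list of 4, in which MCM6 and MCM7 had log2 fold changes of -0.24 and -0.22. Fry's mixed test, which takes members moving either way, passed for heat shock (adjusted p = 0.014). It did not pass for the mitochondrial and cell cycle lists (adjusted p = 0.998 and 0.27). Neither of these lists had a gene past limma or edgeR, with 0 and 2 genes at an unadjusted p under 0.05. The mitochondrial list includes NDL1 itself and FtsH2B (log2 fold change -0.07), which was matched by a symbol pattern. Whether FtsH2B acts in mitochondria was not checked, so this list says little beyond NDL1.

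Of 23 jasmonate genes only opr6, an oxophytodienoate reductase, passed, and it rose from 25.0 ± 4.56 to 160 ± 15.2 (camera adjusted p = 0.63). Adjusted over the list alone, 2 rose and 1 fell. In wildtype replicate 2, the lipoxygenase gene lox10 was at 17573 normalized counts against 1874 and 1580 in the other wildtype libraries and 1028, 1098 and 1678 in Bif1;Bif4. That library also lay apart on the second principal component, which held 24.4% of the variance, while the genotypes separated on the first (48.2%). Among markers of leaf tissue, 0 of 11 photosynthesis genes passed with limma or edgeR, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.38). Of the 11, psat1 and Pep1 (log2 fold changes -0.02 and 0.32) are of doubtful identity. Camera without them gave adjusted p = 0.53.

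**Figure D3:**
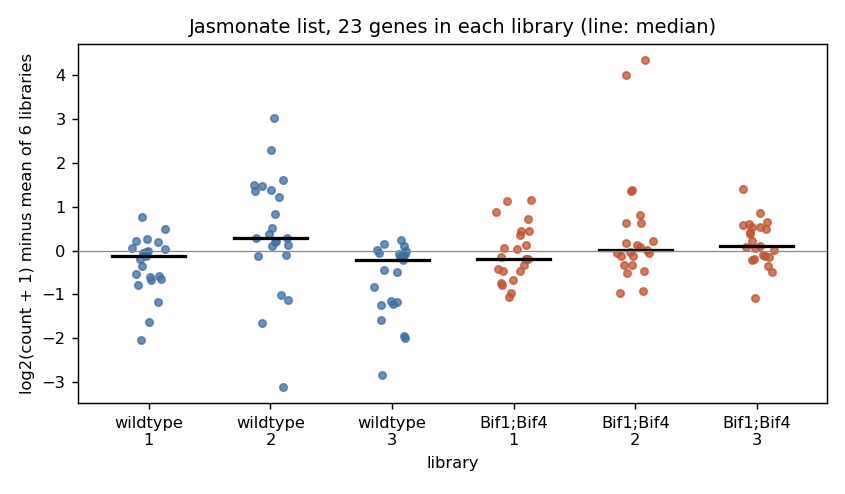
Deviation of each of 23 jasmonate genes from its mean over the 6 libraries, on the log2(count + 1) scale, per library. Points are genes and lines are medians, which were 0.29 in wildtype replicate 2 and -0.11 and -0.21 in the other wildtype libraries.

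Further named genes with large rises were PLTZ1 (12.1 ± 8.01 to 99.7 ± 2.34), the ethylene synthesis gene acs7 (20.7 ± 10.8 to 84.2 ± 21.9), the cell wall invertase gene incw1 (21.1 ± 5.63 to 85.4 ± 20.2), AR2 (84.9 ± 30.8 to 236 ± 32.9) and ERD3 (47.2 ± 13.8 to 155 ± 68.1). LOB15 and the hemoglobin gene GLB1 rose by 2.01 and 1.56 on the log2 scale with limma and were not called by edgeR (adjusted p = 0.055 and 0.054). Without wildtype replicate 2, ERD3 and GLB1 were not called (adjusted p = 0.056 and 0.054). Other lists with 1 or 2 tested members and no call were lignin (PAL1 and BM1, -0.28 and 0.50), brassinosteroid (na1, -0.36) and secondary wall (CesA12, 0.73, adjusted p = 0.52, and 0.045 without wildtype replicate 2). The only tested tapetum marker was again ocl4, and no SAUR gene of the fixed list was tested.

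The 1104 calls were of genes whose groups did not overlap, as 26.9% of all tested genes were, where chance gives 10% for 3 against 3. A change of at least 2-fold was seen for 168 risen and 339 fallen genes. The edgeR test on recovered reads called 428 risen and 630 fallen genes, and 1039 genes were called by both tools. At an adjusted p under 0.05, the authors' deposited table holds 967 risen and 1096 fallen genes, and 1093 of the genes called by limma were among them, all with the same sign. The counts rested on the library set. Without wildtype replicate 2 there were 776 risen and 627 fallen genes, and 902 of the 1104 calls were kept. The risen count dropped to 203 without wildtype replicate 3 and to 167, 171 and 261 without Bif1;Bif4 replicates 1, 2 and 3, and the fallen count was 368, 306, 291, 282 and 336 without wildtype replicates 1 and 3 and Bif1;Bif4 replicates 1 to 3.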

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

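Of the alternatives, the edgeR test with TMM scaling and the removal of doubtful list members were chosen after seeing the data. All 44 named genes past the test kept their sign in every alternative that gave a value; 44 stayed past it with DESeq2, 41 with edgeR and 33 without Bif1;Bif4 replicate 1 or 2. The counts of risen and fallen genes stayed within 1.5 times of 467 and 637 with median-centring, limma-voom, edgeR, both other filters and both pseudocounts. DESeq2 on recovered reads called 1001 risen and 1117 fallen genes, of which 2025 were in the authors' deposited table; the cause was not tested. A threshold of 0.01 left 94 risen and 180 fallen genes, and a fold of at least 2 left 168 and 339, by construction. Leaving out a library gave 167 to 776 risen and 282 to 627 fallen genes and 446 to 1095 genes shared with the authors' table; fewer libraries were then fitted. With an estimated correlation no list passed in camera. The axillary, meristem, polarity, Aux/IAA and epidermis lists each had adjusted p = 0.27 there, with unadjusted p from 0.019 to 0.090. With fry these lists were lower, at adjusted p = 0.0095, 0.027, 0.016, 0.023 and 0.022 in that order. The anthocyanin list passed with fry (0.016), DESeq2 (0.033), limma-voom (0.019) and edgeR (0.020 with TMM and 0.021 with relative log scaling). Fry's mixed test passed for lists that camera at the preset correlation did not call. These were auxin response factors (adjusted p = 2.1e-06), jasmonate (6.4e-06), SBP (4.2e-05), auxin transport and floral MADS (both 1.0e-04) and cytokinin (1.6e-04). Anthocyanin (0.0017), expansin (0.0073) and heat shock (0.014) passed it too. Aux/IAA (0.054), gibberellin (0.063), cell cycle (0.27), photosynthesis (0.40) and the mitochondrial list (0.998) did not. The expansin list was lower with DESeq2 (0.033), and the epidermis list was lost with a minimum of 50 (0.087). Over libraries left out, adjusted p ran from 0.0016 to 0.053 for Aux/IAA and from 0.0078 to 0.057 for epidermis, lost without wildtype replicate 2; the cause was not tested. BIF4 passed with DESeq2 (log2 fold change -0.74, adjusted p = 0.020). With the replicate number as a block there were 381 risen and 429 fallen genes. Deviations of same-numbered libraries correlated at 0.07, -0.17 and -0.03 across genes, while those of differently numbered libraries ran from -0.31 to 0.26. These values show no pairing by number but cannot exclude it. With about 3 normalized counts as the limit of a 0, the level of BA1, ra1 and bd1 in Bif1;Bif4 is not resolved, nor is that of PIN10a in wildtype. Values of ra3 in Bif1;Bif4 (4.86, 3.97 and 1.96) lie close to this limit, so the size of its fall is only roughly known.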

Other observations

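All tests below except that of the photosynthesis list were chosen after the result was seen, and the rules for how far a value must clear its bound were changed afterwards for the photosynthesis, later-stage and KNOX tests, which left these explanations open. The 10 splits of the 6 libraries are too few for a share under 0.05: the real split gave 1104 genes past the test, 1 split gave as many (the real one), and the highest of the other splits gave 0.

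Families were also examined after their values were seen, and of those with GRF and NF-YA names 0 genes were in a fixed list. Of 6 genes of the NF-YA subunit of the CCAAT-binding factor, 4 rose and 0 fell, and 4 rose without wildtype replicate 2. NF-YA11 rose from 325 ± 46.2 to 674 ± 81.4 normalized counts, and the gene GRMZM5G853836, named NF-YA4, from 765 ± 145 to 1716 ± 96.6 (limma adjusted p = 0.0052 and 0.0041). Among 18 genes with GRF symbols, which name both growth-regulating factors and 14-3-3 proteins, 5 fell and 1 rose, and 6 fell and 4 rose without wildtype replicate 2. GRMZM2G034876 (GRF1) fell from 1419 ± 244 to 412 ± 86.1, while GF14-12, a 14-3-3 gene, rose by 0.66 on the log2 scale. Of 17 genes with AUX symbols, 7 of them already in a fixed list, 2 rose and 4 fell, and of 17 TIFY genes, 6 of them already in a fixed list, 0 passed with limma or edgeR, with 4 at an unadjusted p under 0.05 and 1 fallen without wildtype replicate 2.

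Wildtype replicate 2 stood apart from the other wildtype libraries. It differed over 2-fold from them in 1543 and 1566 genes, while they differed from each other in 772. Besides lox10, the lipoxygenase gene lox5 was at 11191 normalized counts there against 3055 and 1944, and aos1, for allene oxide synthase, at 1082 against 203 and 90.8. The median of the jasmonate list lay above each of 10000 random lists matched on expression, as did that of the expansin list, and the heat shock list lay at percentile 0.01. The auxin response factor, auxin transport, organ polarity and mitochondrial lists were also high, at percentiles 99.99, 99.6, 99.0 and 98.6, among 18 lists examined. RIP was at 1970 against 68.3 and 16.5 in the other wildtype libraries and at 653, 757 and 1111 in Bif1;Bif4.

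Depth and scaling do not account for that gap: after thinning to 21047225 reads and median-centring at least 1493 genes still differed over 2-fold, against 769 between the other wildtype libraries. Bif1;Bif4 material in the pool would not put 250 genes over 2-fold above the highest of the other 5 libraries, where no other library had more than 51. For the genes that fell in Bif1;Bif4, Bif1;Bif4 material stays open. In wildtype replicate 2, ra3, BA1, baf1, lg2 and lg1 were lower than in both other wildtype libraries. The fallen genes ra1, BIF1, OFP28, CUC2 and yabby15 were higher there than in both. Over 122 genes fallen at least 4-fold without that library the median log2 deviation was 0.024 (SE 0.094), with 50 lower and 58 higher than both. Leaf tissue stays open too. The bound set beforehand, the middle 95% of random lists, was met, with the photosynthesis list at percentile 97.3, but it was wrong as a ground to exclude: the list median of 0.42 lay under the bound of 0.43 by far less than its SE over the 11 genes (0.34), with 3 members over 2-fold higher and 0 lower, lhcb5 at 227 against 160 and 181 and rbcS at 48.5 against 25.3 and 17.5. The members of doubtful identity, psat1 (982 against 917 and 996) and Pep1 (579 against 566 and 576), were not left out of this test. The verdict on this test was changed more than once after its value was seen. A later stage of the pooled tassels also stays open, with the axillary list at percentile 11.0 and the floral MADS list at 26.2, both with members going each way.

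The fall of the axillary meristem list was weighed against 3 explanations. All 13 fallen members stayed past the test without wildtype replicate 2, so that library does not account for it. A scaling factor moves all genes of a library alike, but the list median of -1.39 lay at percentile 0 of 10000 random lists matched on expression, the lowest of which was -0.30. A smaller share of all KNOX-expressing meristem tissue could account for part: 8 KNOX genes had a median log2 fold change of -0.73, from -1.66 to -0.09, against -1.94 for the fallen members, and this spread decides nothing. The sets share 2 genes, lg3 and lg4. With these left out of both, the KNOX median was -0.62 (SD 0.62). With the SD added it just missed 50% of the fall of the other members (-1.25 on the log2 scale), with called KNOX genes left out. This comparison cannot decide, since its axillary members were picked because they fell and the KNOX genes were not. Whether fewer axillary meristems formed or the genes were lowered within them cannot be told from pooled tassels, and a direct effect of the mutant proteins was not tested.

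The authors' deposited table gives smaller fold changes than the limma fit for low genes. Among called genes over 2-fold, the median ratio of the deposited to the fitted log2 fold change was 0.51 for 251 genes with a mean under 100, 0.79 for 228 genes from 100 to 1000 and 0.91 for 28 genes above. The deposited table gives no p for 99 genes with reads, and 86 of these had their highest value in wildtype replicate 2.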
